A study of Mus musculus with 25 samples.

How the data were processed

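The deposited values are summarised intensities on a linear scale, 1 per probe set and array, for 12488 probe sets on 25 arrays. The authors had scaled the arrays: the mean intensity without the lowest and highest 2% of probe sets lay between 500.23 and 500.36 on each deposited array, as the values show. The software and scanner are not given in the sources used here. The labels name separate mice, numbered within each age, and whether the arrays with markers of both sexes held RNA of more than 1 mouse is not given in the sources used here.

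Intensities were used as deposited, set to a floor at the 20th percentile of the table (32.7 units) and taken to log2. A fold against a group at the floor is a lower bound. The 66 control probe sets were left out, and a probe set was kept when it exceeded the 40th percentile (127.8 units) on at least 3 arrays, which left 8835. Arrays had 1.01% to 3.7% of these at the floor. Gene names came from the platform's annotation, which lists 10855 probe sets with 1 symbol and 396 with several, and leaves 1237 unnamed here. Symbols of 10839 were matched through their gene number to the GRCm38.p6 gene table, used for names alone. No gene was named from a probe set with several symbols, and a gene was represented by its probe set with the highest mean. No coordinates are given, since no genome was used here.

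Linear models were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. Ages up to 9 weeks shared 1 fit of 18 arrays, and 9 weeks, 5 months and 1 year another of 10. Adjusted p is by Benjamini-Hochberg, with a threshold of 0.05. The camera test of a list compares its genes with all others, at a preset correlation between genes or an estimated one. Of 31 lists fixed beforehand, 29 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01 and again with an estimated one. The spread between mice was compared with a 1-sided F test on pooled variances within ages, and a list's median ratio was ranked among 10000 random lists of like expression.

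Genes were named by a rule set before the data were examined, as were the comparisons, the lists and the alternative settings, apart from those said to be chosen later. It took the 10 largest increases and decreases (5 in all but 2 comparisons) among called genes whose groups did not overlap, up to 4 called members of each called list, 16 hair cycle genes for growth against 9 weeks where measured, and the 10 largest variance ratios. A gene outside this rule is said to be chosen after its values were seen. Between 28.7% and 56.7% of probe sets had groups that did not overlap, where chance gives 10% with 3 arrays against 3, 5.71% for 1 year against 5 months and 2.38% for growth against 9 weeks.

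On simulated data of 8835 probe sets, limma recovered 20.9%, 62.7% and 100% of log2 changes of 0.5, 1 and 2 for day 17 against day 14, and 0%, 44.8% and 89.4% for 1 year against 5 months. The variance test recovered 6% of ratios of 4 and 65% of ratios of 16. Alternatives covered quantile normalisation, centring on medians, a pseudocount, the filter, the trend, array weights, the arrays fitted together, the replicate number as a block, probe sets of a gene averaged, a floor at the 40th percentile, and each mouse left out. A covariate for both sex markers, the hair shaft score as a covariate for the macrophage score, and other choices of young ages for the variance test were added after the data were seen.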

Results

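Total RNA from whole back skin was measured on 25 short-oligonucleotide arrays, each labelled as 1 mouse. Skin was taken on postnatal days 1, 6, 14, 17 and 23, at 9 weeks, 5 months and 1 year, with 3 arrays per age and 4 at 1 year. Hair follicles of young mice pass together through growth (anagen), regression (catagen) and rest (telogen), and older mice lose this synchrony, as is known from the biology of the follicle. Postnatal age differs in every comparison below, so no difference can be assigned to hair phase alone. The array median lay between 180.05 and 252 intensity units, and the Pearson correlation between log2 values of 2 arrays of the same age lay between 0.844 and 0.968. The highest intensity was 22033.5 to 36049 on arrays of days 1, 17 and 23 and 5 months, and 41699.8 to 78877 on the others. The ribosomal protein list passed camera in each comparison across these sets of ages and in none within a set. Whether the sets were processed apart is not given in the sources used here, and such a difference cannot be told from age. The number of arrays limits the precision. The female marker Xist and the male marker Eif2s3y, looked up after values were seen, were both above the floor on 8 arrays: all of days 6 and 17, and mice 1 and 3 of day 1. Each other array had 1 of the markers. As 1 mouse would give 1 of them, the arrays with both may hold RNA of more than 1 mouse. Below, a mouse is the sample so labelled, and n counts arrays.

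Of 8835 probe sets tested, 6996 differed among the 6 ages up to 9 weeks (limma F test, adjusted p under 0.05), and the age means of 1256 of these spanned at least 4-fold. The highest mean fell on day 1 for 1563 of them, on day 6 for 779, on day 14 for 1086, on day 17 for 1118, on day 23 for 1213 and at 9 weeks for 1237. With arrays centred on their medians, the number highest on day 1 was 970. Of the 29 gene lists tested, those of epidermal differentiation, basal keratinocytes, regulators linked to follicle regression, T cells, B cells, red blood cells, and nerve and Schwann cells passed the test in no comparison.

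**Figure D1:**
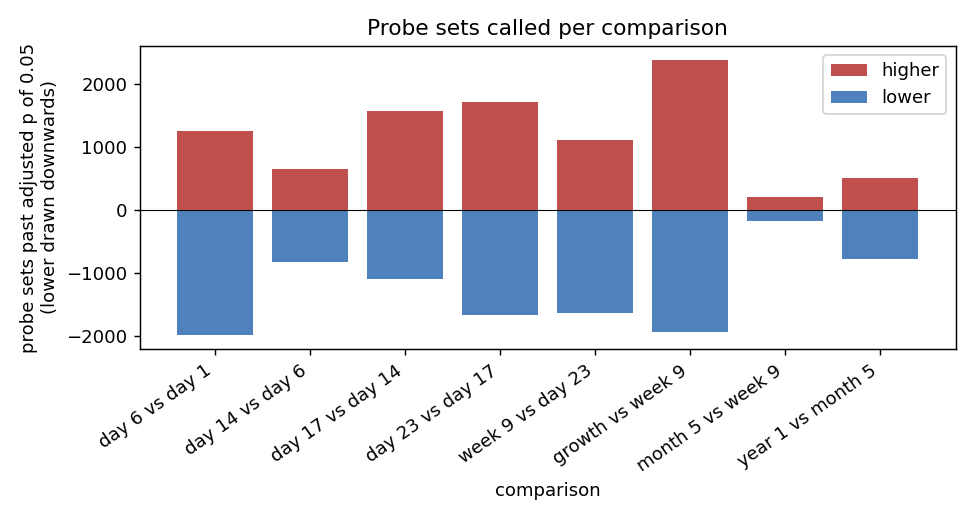
Bars give the number of probe sets past an adjusted p of 0.05 in each comparison, higher upwards and lower downwards, on a linear axis. The count was 4326 for growth against 9 weeks and 380 for 5 months against 9 weeks.

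Day 6 against day 1 covers the time when follicles begin to make hair shafts. Krtap6-2, a keratin-associated protein of hair, went from 124.1 ± 24.3 to 18500 ± 2481 intensity units (SD, n = 3), a log2 change of 7.23 ± 1.01 (SE). Krt83, a hair keratin, rose by 7.85 ± 1.2 and Krtap9-1 by 8.13 ± 1.32. The SEs of hair genes between young ages use the spread shared by all ages up to 9 weeks. At 9 weeks mouse 3 had 7360.9 units of Krtap6-2 and mice 1 and 2 had 92.5 and 138.5, which widens these SEs. Of 21 hair shaft keratins and keratin-associated proteins 20 rose and 1 did not pass, or 21 adjusted over the list alone. For the hair shaft list camera gave adjusted p = 5.57e-13, and adjusted p = 0.246 with an estimated correlation. Of 9 inner root sheath genes 5 rose, or 6 adjusted over the list alone, with Padi1 and Krt72 at 3.29 ± 0.66 and 3.02 ± 0.62. The inner root sheath list had adjusted p = 7.12e-04 in camera, and adjusted p = 0.337 with an estimated correlation. Of 28 follicle signals and transcription factors 12 rose and 3 fell, or 13 and 4 adjusted over the list alone, with Foxq1 at 2.88 ± 0.32 and Foxn1, needed for shaft differentiation, at 2.61 ± 0.49. Camera gave the follicle signal list adjusted p = 0.0036, and adjusted p = 0.322 with an estimated correlation.

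Pigment cell genes rose in 5 of 10 cases, also 5 adjusted over the list alone, with Trpm1 at 1.39 ± 0.27 and Oca2 at 1.34 ± 0.32. For the pigment cell list camera gave adjusted p = 0.0237, and adjusted p = 0.246 with an estimated correlation. Cholesterol synthesis genes rose in 10 of 16 cases, or 11 adjusted over the list alone, with Fdps at 1.2 ± 0.14 and Sqle, the squalene epoxidase, at 1.05 ± 0.19. The cholesterol synthesis list had adjusted p = 2.40e-04 in camera, and adjusted p = 0.246 with an estimated correlation. Genes of class II antigen presentation rose in 5 of 11 cases, or 6 adjusted over the list alone, with H2-Aa at 3.33 ± 0.2 and the invariant chain Cd74 at 1.22 ± 0.18. Camera gave the class II list adjusted p = 0.0036, and adjusted p = 0.194 with an estimated correlation. Ribosomal protein genes rose in 18 of 26 cases and fell in 3, or 18 and 4 adjusted over the list alone. For the ribosomal protein list camera gave adjusted p = 7.43e-06, and adjusted p = 0.163 with an estimated correlation. Genes of oxidative phosphorylation rose in 26 of 69 cases and fell in 11, or 26 and 12 adjusted over the list alone. The oxidative phosphorylation list had adjusted p = 0.0045 in camera, and adjusted p = 0.337 with an estimated correlation. Quantile normalisation ended both of these calls, with median changes of 0.1 instead of 0.5 for ribosomal proteins (adjusted p = 0.607) and 0.08 instead of 0.17 for oxidative phosphorylation (adjusted p = 0.729). The ratio of the 3' over the 5' probe set, a sign of RNA quality, was 0.85 ± 0.04 on day 1 and 1.03 ± 0.12 on day 6 for Gapdh, and 1.01 ± 0.05 and 1.21 ± 0.12 for Actb (SD, n = 3).

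Genes of developing muscle fell in 8 of 10 cases, or 9 adjusted over the list alone, with Myh3, the embryonic myosin heavy chain, at 1523.7 ± 105.9 units on day 1 and 78.7 ± 14.2 on day 6 (SD, n = 3). The call of this list held in both forms of the test (camera, adjusted p = 7.43e-06, and adjusted p = 0.0416 with an estimated correlation). Skeletal muscle genes fell in 22 of 27 cases and rose in 2, the same numbers adjusted over the list alone, with Ryr1, the calcium release channel, lower by a log2 change of -1.89 ± 0.16. Camera gave the skeletal muscle list adjusted p = 1.26e-09, and adjusted p = 0.194 with an estimated correlation. Mast cell genes fell in 5 of 7 cases, also 5 adjusted over the list alone, with the protease Cpa3 at -2.56 ± 0.23 and Hdc, which makes histamine, at -2.23 ± 0.4. For the mast cell list camera gave adjusted p = 0.0016, and adjusted p = 0.163 with an estimated correlation. Macrophage and dendritic cell genes fell in 9 of 14 cases, also 9 adjusted over the list alone, with Mrc1, the mannose receptor, at -1.76 ± 0.31 and Ctss at -1.17 ± 0.21. The macrophage list had adjusted p = 0.0016 in camera, and adjusted p = 0.337 with an estimated correlation. Dermal collagen and matrix genes fell in 14 of 32 cases, or 18 adjusted over the list alone, with Lox, which cross-links collagen, at -1.21 ± 0.2 and Thbs2 at -0.9 ± 0.17. Camera gave the matrix list adjusted p = 0.0016, and adjusted p = 0.322 with an estimated correlation.

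Dermal papilla genes fell in 6 of 12 cases, with 6 lower and 1 higher adjusted over the list alone, among them Igfbp3 at -1.88 ± 0.14 and Ptch1, the hedgehog receptor, at -1.52 ± 0.15. For the dermal papilla list camera gave adjusted p = 0.0233, and adjusted p = 0.163 with an estimated correlation. After quantile normalisation this list did not pass (adjusted p = 0.0733). Endothelial genes fell in 7 of 12 cases, with 7 lower and 1 higher adjusted over the list alone, among them Tie1 at -1.37 ± 0.24 and Cdh5, a cadherin of vessels, at -0.89 ± 0.16. The endothelial list had adjusted p = 0.0479 in camera, and adjusted p = 0.246 with an estimated correlation. The endothelial call was ended by quantile normalisation (adjusted p = 0.147), by a higher floor (adjusted p = 0.0699), by averaging the probe sets of a gene (adjusted p = 0.103) and by a covariate for both sex markers (adjusted p = 0.0506). It was also lost, with an adjusted p between 0.0513 and 0.0748, without mouse 1 or 3 of day 1, mouse 3 of day 6, mouse 1 of day 14, mouse 2 or 3 of day 17, mouse 3 of day 23, or mouse 1 or 3 of 9 weeks, whose spread enters the fit. In limma, 1248 probe sets were higher and 1987 lower. The share of higher calls was 38.6%, and it was 50.4% after quantile normalisation and 59.5% with arrays centred on their medians, which moved the median change of all probe sets from -0.151 to 0.03. With that centring the median change was -0.26 instead of -0.43 for matrix, -0.34 instead of -0.51 for endothelial, 0.35 instead of 0.17 for oxidative phosphorylation and 0.68 instead of 0.5 for ribosomal proteins, and no list that passed changed its direction.

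Between day 6 and day 14 follicles stay in growth. Dermal collagen and matrix genes fell in 23 of 32 cases, also 23 adjusted over the list alone, with Col6a2, a chain of collagen VI, at 4526 ± 157.2 units on day 6 and 1343 ± 195.4 on day 14 (SD, n = 3), and with Lum, a matrix proteoglycan, lower by a log2 change of -1.59 ± 0.13 (SE). Their adjusted p was 5.27e-13 (camera), and adjusted p = 0.0578 with an estimated correlation. Adipocyte genes fell in 11 of 20 cases and rose in 1, the same numbers adjusted over the list alone, with the hormone Adipoq at -1.56 ± 0.17 and Slc2a4, the insulin-regulated glucose transporter, at -2.03 ± 0.17, the latter not past the test with a higher floor. Camera gave the adipocyte list adjusted p = 0.0013, and adjusted p = 0.299 with an estimated correlation. Cell division genes fell in 12 of 41 cases, or 16 adjusted over the list alone. For the cell division list camera gave adjusted p = 5.90e-06, and adjusted p = 0.146 with an estimated correlation. Krt1 and Flg, which encode proteins of the cornifying epidermis, fell by 4.38 ± 0.19 and 3.23 ± 0.2, while Sprr2h, a small proline-rich protein, rose by 3.6 ± 0.55. Agt, the precursor of angiotensin, and Igf2, a growth factor, changed by -3.14 ± 0.41 and -1.77 ± 0.17.

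Dermal papilla genes fell in 5 of 12 cases, or 6 adjusted over the list alone, with Vcan at -1.62 ± 0.23 and Sox18 at -1.36 ± 0.12. The dermal papilla list had adjusted p = 0.0076 in camera, and adjusted p = 0.0578 with an estimated correlation. Genes of developing muscle fell in 6 of 10 cases, or 7 adjusted over the list alone, with Myh8, the perinatal myosin heavy chain, at -2.11 ± 0.31. Camera gave the developing muscle list adjusted p = 2.49e-04, and adjusted p = 0.0578 with an estimated correlation. Genes of mature skeletal muscle rose in 7 of 27 cases, with 7 higher and 1 lower adjusted over the list alone, among them the fast myosin heavy chains Myh4 at 3.57 ± 0.23 and Myh1 at 1.91 ± 0.16, with a median change of 0.05. For the skeletal muscle list camera gave adjusted p = 0.0097, and adjusted p = 0.561 with an estimated correlation. Without mouse 2 of day 14 the skeletal muscle list did not pass (adjusted p = 0.0989). Mast cell genes fell in 4 of 7 cases, also 4 adjusted over the list alone, with Cma1 at -1.77 ± 0.25 and Cpa3 at -1.45 ± 0.23 (camera, adjusted p = 0.0122, and adjusted p = 0.176 with an estimated correlation), and averaging the probe sets of a gene ended this call (adjusted p = 0.0536). Genes of class II antigen presentation rose in 3 of 11 cases, also 3 adjusted over the list alone, with H2-Aa at 0.95 ± 0.2 and Cd74 at 0.94 ± 0.18. The class II list had adjusted p = 0.0035 in camera, and adjusted p = 0.146 with an estimated correlation.

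The hair shaft list passed with 2 of 21 members higher, also 2 adjusted over the list alone, one of them Krt84 at 1.48 ± 0.14. Camera gave the hair shaft list adjusted p = 0.0404, and adjusted p = 0.725 with an estimated correlation. This call was lost after quantile normalisation (adjusted p = 0.0815), and without mouse 2 of day 6 (adjusted p = 0.059), mouse 3 of day 6 (adjusted p = 0.095) or mouse 2 of day 14 (adjusted p = 0.0989). In limma, 647 probe sets were higher and 817 lower on day 14, and 951 were called in all when the 25 arrays shared 1 fit. Every array of day 6 held both sex markers and no array of day 14 did.

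The comparison of day 17 with day 14 covers the onset of follicle regression. Every array of day 17 held both sex markers and no array of day 14 did, so that difference goes with age here. Cell division genes fell in 21 of 41 cases, or 22 adjusted over the list alone, with Rrm1 and Rrm2, the subunits of ribonucleotide reductase, at -1.74 ± 0.23 and -1.22 ± 0.18 (log2 change and SE, 3 mice per age), and Cdc20 at -1.22 ± 0.16. For the cell division list camera gave adjusted p = 2.76e-10, and adjusted p = 0.0992 with an estimated correlation. Pigment cell genes fell in 6 of 10 cases and rose in 1, the same numbers adjusted over the list alone, with Dct, an enzyme of melanin synthesis, at 2987 ± 384.6 units on day 14 and 1001 ± 59.5 on day 17, and Pmel at -1.73 ± 0.2. The pigment cell list had adjusted p = 0.0106 in camera, and adjusted p = 0.254 with an estimated correlation. Cholesterol synthesis genes fell in 6 of 16 cases and rose in 1, or 9 and 1 adjusted over the list alone, with Fdps at -1.26 ± 0.14 and Sqle at -1.14 ± 0.19. Camera gave the cholesterol synthesis list adjusted p = 3.16e-04, and adjusted p = 0.294 with an estimated correlation. Ribosomal protein genes fell in 19 of 26 cases and rose in 2, or 19 and 4 adjusted over the list alone, with Rps10 at -1.11 ± 0.1. For the ribosomal protein list camera gave adjusted p = 2.05e-10, and adjusted p = 0.0874 with an estimated correlation. Genes of oxidative phosphorylation fell in 30 of 69 cases and rose in 5, or 31 and 6 adjusted over the list alone, with Cyc1, cytochrome c1, at -0.88 ± 0.1 and Ndufa8 at -0.87 ± 0.08. The oxidative phosphorylation list had adjusted p = 1.82e-05 in camera, and adjusted p = 0.254 with an estimated correlation. Beside these lists, the 3' over 5' ratio was 0.93 ± 0.01 on day 14 and 0.82 ± 0.05 on day 17 for Gapdh, and 1.24 ± 0.06 and 1.15 ± 0.07 for Actb (SD, n = 3).

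Skeletal muscle genes rose in 17 of 27 cases, or 19 adjusted over the list alone, with Ryr1 at 1.59 ± 0.16 and Tnnc2, a fast troponin, at 1.25 ± 0.13. Camera gave the skeletal muscle list adjusted p = 7.93e-08, and adjusted p = 0.254 with an estimated correlation. Adipocyte genes rose in 11 of 20 cases and fell in 1, or 14 and 1 adjusted over the list alone, with Slc2a4 at 2.39 ± 0.17 and Adipoq at 1.18 ± 0.17. For the adipocyte list camera gave adjusted p = 2.83e-04, and adjusted p = 0.292 with an estimated correlation. Dermal collagen and matrix genes rose in 15 of 32 cases, also 15 adjusted over the list alone, with Dpt at 1.07 ± 0.16 and Dcn, decorin, at 0.9 ± 0.08. The matrix list had adjusted p = 3.16e-04 in camera, and adjusted p = 0.294 with an estimated correlation. Macrophage and dendritic cell genes rose in 8 of 14 cases, or 9 adjusted over the list alone, with Lyz2, a lysozyme of phagocytes, at 1.46 ± 0.18 and Cd14 at 1.16 ± 0.12. Camera gave the macrophage list adjusted p = 0.001, and adjusted p = 0.36 with an estimated correlation. Interferon response genes rose in 9 of 15 cases, also 9 adjusted over the list alone, with Psmb9 at 1.95 ± 0.49 (2.75 without mouse 1 of day 14) and Ifi204 at 1.56 ± 0.33 (camera, adjusted p = 0.0106, and adjusted p = 0.36 with an estimated correlation), and a higher floor ended this call (adjusted p = 0.097). Endothelial genes rose in 4 of 12 cases, or 5 adjusted over the list alone, with Sox17 at 1.25 ± 0.16 and Tie1 at 1.24 ± 0.24. For the endothelial list camera gave adjusted p = 0.0349, and adjusted p = 0.254 with an estimated correlation. The endothelial call was lost after quantile normalisation (adjusted p = 0.0747), with a higher floor (adjusted p = 0.0571) and with the probe sets of a gene averaged (adjusted p = 0.112).

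Among the largest increases were those of Zbtb16, a transcriptional repressor, at 2.62 ± 0.33, Foxc2 at 3.23 ± 0.43 and Spock2 at 3.09 ± 0.31. Ucp1, the uncoupling protein of brown fat, lay at the floor in all 3 mice on day 14 and at 517.9 ± 231.7 units on day 17, a log2 change of at least 3.87 ± 0.73. The largest decreases were those of Utp14a at -2.17 ± 0.31, Zbtb17 at -2.15 ± 0.49, Nr1h4, a bile acid receptor, at -2.05 ± 0.32 and Uqcc1 at -2.03 ± 0.33. In limma, 1574 probe sets were higher and 1097 lower. The share of higher calls was 58.9%, and it was 48.9% after quantile normalisation and 36.5% with arrays centred on their medians, which moved the median change of all probe sets from 0.12 to -0.04. With that centring the median change was 0.23 instead of 0.39 for matrix, 0.36 instead of 0.52 for endothelial and -0.33 instead of -0.17 for oxidative phosphorylation, cholesterol synthesis genes were lower in 10 cases, and no list that passed changed its direction.

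The comparison of day 23 with day 17 runs from regression into rest. All 21 hair shaft keratins and keratin-associated proteins fell, also 21 adjusted over the list alone. The hair shaft list had adjusted p = 3.59e-14 in camera, and adjusted p = 0.216 with an estimated correlation. All 9 inner root sheath genes fell, also 9 adjusted over the list alone, with Krt71, a keratin of that sheath, at 26154 ± 863 units on day 17 and 239.7 ± 37.8 on day 23 (SD, n = 3). Their adjusted p was 5.89e-07 (camera), and adjusted p = 0.216 with an estimated correlation. Of 28 follicle signals and transcription factors 18 fell, or 21 adjusted over the list alone, with Foxn1 at -3.65 ± 0.49 (log2 change and SE) and Dlx3, a homeobox factor, at -3.34 ± 0.38. Camera gave the follicle signal list adjusted p = 1.91e-07, and adjusted p = 0.216 with an estimated correlation. Pigment cell genes fell in 5 of 10 cases, also 5 adjusted over the list alone, with Mitf, the regulator of the melanocyte lineage, at -1.96 ± 0.33 and Mc1r at -1.15 ± 0.27. For the pigment cell list camera gave adjusted p = 0.0116, and adjusted p = 0.216 with an estimated correlation.

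Skeletal muscle genes rose in 21 of 27 cases and fell in 2, the same numbers adjusted over the list alone, with Pgam2 at 2.19 ± 0.14 and Pygm, the muscle glycogen phosphorylase, at 2.08 ± 0.14. The skeletal muscle list had adjusted p = 7.67e-10 in camera, and adjusted p = 0.216 with an estimated correlation. Genes of oxidative phosphorylation rose in 39 of 69 cases and fell in 2, or 42 and 4 adjusted over the list alone, with Sdha at 1.3 ± 0.19 and Ndufv3 at 1.09 ± 0.16. Camera gave the oxidative phosphorylation list adjusted p = 5.89e-07, and adjusted p = 0.216 with an estimated correlation. From day 17 to day 23 the 3' over 5' ratio went from 0.82 ± 0.05 to 0.88 ± 0.01 for Gapdh and from 1.15 ± 0.07 to 1.1 ± 0.08 for Actb (SD, n = 3). Dermal collagen and matrix genes rose in 22 of 32 cases, or 23 adjusted over the list alone, with Fmod at 2.74 ± 0.42 and Lox at 1.68 ± 0.2. For the matrix list camera gave adjusted p = 1.91e-07, and adjusted p = 0.216 with an estimated correlation. Adipocyte genes rose in 14 of 20 cases and fell in 2, or 15 and 2 adjusted over the list alone, with the hormone Retn at 1.88 ± 0.25 and Fasn, the fatty acid synthase, at 1.42 ± 0.17. The adipocyte list had adjusted p = 1.18e-04 in camera, and adjusted p = 0.216 with an estimated correlation. Macrophage and dendritic cell genes rose in 7 of 14 cases, also 7 adjusted over the list alone, with Lyz2 at 1.4 ± 0.18 and C1qa at 1.31 ± 0.24. Camera gave the macrophage list adjusted p = 0.024, and adjusted p = 0.449 with an estimated correlation. Dbp, a transcription factor of the circadian output, had a mean of 21.9 ± 13.4 units on day 17 and 495.3 ± 68.3 on day 23. In limma, 1720 probe sets were higher and 1662 lower. Every array of day 17 held both sex markers and no array of day 23 did.

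**Figure D2:**
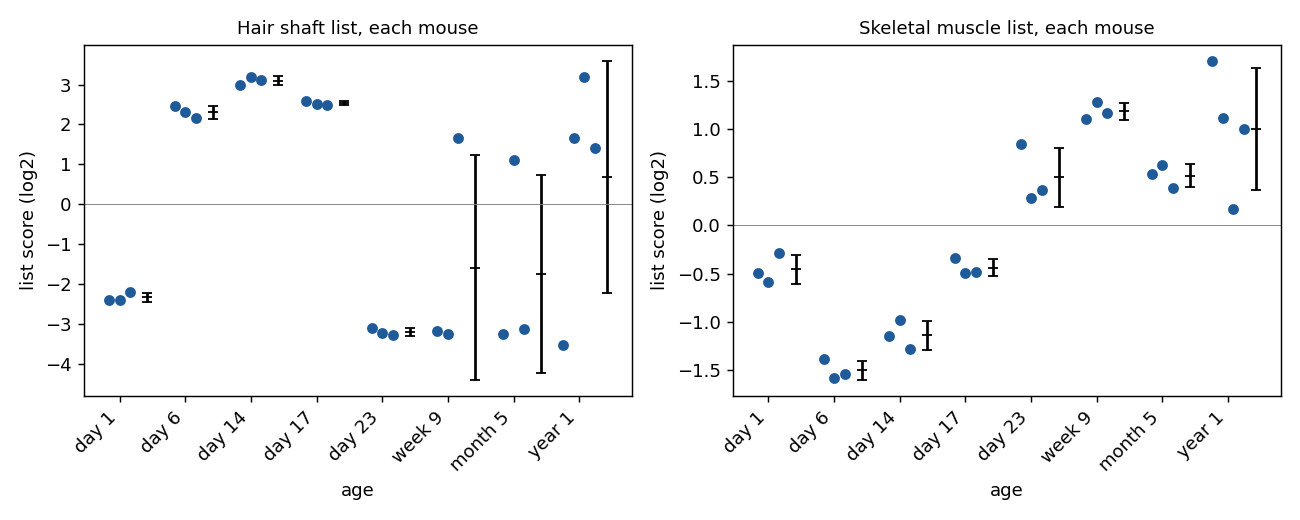
Points are the scores of single mice at each age for the hair shaft and the skeletal muscle list, the mean over members of log2 value minus its mean over 25 arrays; black marks give the mean and SD of 3 mice (4 at 1 year). At 9 weeks mouse 3 had a hair shaft score of 1.67, and mice 1 and 2 had -3.16 and -3.25.

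The comparison of 9 weeks with day 23 sets side by side ages at which follicles are known to rest, although mouse 3 of 9 weeks had a hair shaft score of 1.67, against -3.16 and -3.25 in mice 1 and 2. Dermal collagen and matrix genes fell in 21 of 32 cases and rose in 2, or 22 and 4 adjusted over the list alone, with Eln, which encodes elastin, at 9670 ± 448.8 units on day 23 and 2516 ± 347.8 at 9 weeks (SD, n = 3). Lox was lower by a log2 change of -2.43 ± 0.2 (SE) and Col5a1 by -1.64 ± 0.14 (camera, adjusted p = 4.36e-08 for the list, and adjusted p = 0.167 with an estimated correlation). Skeletal muscle genes rose in 18 of 27 cases, or 20 adjusted over the list alone, with Tnnt3 at 1.28 ± 0.1 and Actn3 at 1.22 ± 0.2. For the skeletal muscle list camera gave adjusted p = 1.45e-09, and adjusted p = 0.197 with an estimated correlation. Genes of oxidative phosphorylation rose in 31 of 69 cases and fell in 2, or 34 and 5 adjusted over the list alone, with Atp5e at 1.51 ± 0.15. The oxidative phosphorylation list had adjusted p = 2.22e-08 in camera, and adjusted p = 0.167 with an estimated correlation. Ribosomal protein genes rose in 16 of 26 cases and fell in 1, or 16 and 2 adjusted over the list alone, with Rps18 at 0.98 ± 0.08. Camera gave the ribosomal protein list adjusted p = 2.22e-08, and adjusted p = 0.167 with an estimated correlation. After quantile normalisation the ribosomal median was 0.09 instead of 0.55 and the list did not pass (adjusted p = 0.361). The 3' over 5' ratio was 0.88 ± 0.01 on day 23 and 1.02 ± 0.07 at 9 weeks for Gapdh, and 1.1 ± 0.08 and 1.05 ± 0.1 for Actb (SD, n = 3).

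Macrophage and dendritic cell genes rose in 7 of 14 cases and fell in 1, the same numbers adjusted over the list alone, with the complement genes C1qc and C1qb at 1.43 ± 0.22 and 1.29 ± 0.29. For the macrophage list camera gave adjusted p = 0.0288, and adjusted p = 0.568 with an estimated correlation. Without mouse 1 of 9 weeks the macrophage median was 0.39 instead of 0.62 and the list did not pass (adjusted p = 0.138), and with a covariate for both sex markers its adjusted p was 0.0533. Genes of the hair follicle bulge fell in 6 of 15 cases, or 7 adjusted over the list alone, with Npnt at -1.13 ± 0.17 and Fst at -1.02 ± 0.19. The bulge list had adjusted p = 0.0464 in camera, and adjusted p = 0.167 with an estimated correlation. The bulge call was lost without mouse 1, 2 or 3 of day 1, mouse 1 of day 6, mouse 3 of day 23 or mouse 3 of 9 weeks (adjusted p between 0.0502 and 0.0934), with the probe sets of a gene averaged (adjusted p = 0.0603) and with the sex marker covariate (adjusted p = 0.0533). The hair shaft list passed with 2 of 21 members higher, or 1 adjusted over the list alone. Camera gave the hair shaft list adjusted p = 0.0014, and adjusted p = 0.572 with an estimated correlation. Its median was 1.57, and without mouse 3 of 9 weeks it was 0.01 (adjusted p = 0.797).

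Inmt, a methyltransferase, rose by 3.99 ± 0.48 and Ifit3, induced by interferon, by 2.46 ± 0.44, while Kdelr3, a retrieval receptor of the endoplasmic reticulum, and Dnajb9, a chaperone partner of the same compartment, fell by 3.29 ± 0.17 and 2.63 ± 0.23. In limma, 1116 probe sets were higher and 1627 lower, and 1585 were called in all when only these ages were fitted. The share of higher calls was 40.7%, and it was 54.6% with arrays centred on their medians, which moved the median change of all probe sets from -0.067 to 0.04. With that centring the median change was -0.23 instead of -0.33 for the bulge, 0.42 instead of 0.31 for oxidative phosphorylation and 0.66 instead of 0.55 for ribosomal proteins, and no list that passed changed its direction.

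Days 6 and 14, in growth, were then set against 9 weeks. Hair phase and postnatal age differ together in this comparison too, so a difference called higher or lower in growth cannot be assigned to either. All 21 hair shaft keratins and keratin-associated proteins were higher in growth, also 21 adjusted over the list alone. For the hair shaft list camera gave adjusted p = 3.78e-08, and adjusted p = 0.273 with an estimated correlation. Of 9 inner root sheath genes 8 were higher, also 8 adjusted over the list alone. The inner root sheath list had adjusted p = 2.67e-04 in camera, and adjusted p = 0.273 with an estimated correlation. Krt27, a keratin of that sheath, had means of 17489 ± 373 units on day 6, 32631 ± 3897 on day 14 and 3800 ± 6386 at 9 weeks (SD, n = 3), where mouse 3 had 11173.7 units and the others 138.7 and 87.9. Of 28 follicle signals and transcription factors 21 were higher, or 22 with 1 lower adjusted over the list alone. Camera gave the follicle signal list adjusted p = 7.38e-07, and adjusted p = 0.0913 with an estimated correlation. Among genes fixed beforehand for this comparison, Krt71 was higher by a log2 change of 6.35 ± 0.98 (SE), Msx2, a homeobox factor, by 4.58 ± 0.51, Wnt11 by 2.85 ± 0.4, Foxn1 by 2.81 ± 0.43, Shh, a signal of the growing follicle, by 2.02 ± 0.45 and Lef1 by 1.69 ± 0.11. Without mouse 3 of 9 weeks the changes were 8.67 for Krt71, 7.75 for Krt27, 5.75 for Msx2, 3.41 for Foxn1, 2.62 for Shh and at least 3.62 for Wnt11, and the median was 6.07 instead of 4.4 for the hair shaft and 5.48 instead of 4.25 for the inner root sheath list. Without mouse 1 of 9 weeks they were 5.37 for Krt71, 4.59 for Krt27, 3.99 for Msx2, 2.04 for Foxn1 and 1.26 for Shh, and without mouse 2 they were 5.02 for Krt71, 4.26 for Krt27 and 3.99 for Msx2. The hair shaft median was 3.6 without mouse 1 or 2, and the inner root sheath median 3.51 without mouse 2. Bmp4 was higher by 0.36 ± 0.13 and did not pass without mouse 3 of day 6, mouse 2 of day 14 or mouse 3 of 9 weeks. Hoxc13, Fgf5 and Fgf7, also fixed beforehand, were not among the probe sets tested.

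Pigment cell genes were higher in 9 of 10 cases, also 9 adjusted over the list alone, with Tyrp1 at 3.88 ± 0.51, Dct at 2.23 ± 0.15 and Tyr, the tyrosinase, at 1.77 ± 0.3. For the pigment cell list camera gave adjusted p = 1.42e-05, and adjusted p = 0.0413 with an estimated correlation. Cell division genes were higher in 35 of 41 cases, or 36 adjusted over the list alone, with Mad2l1, a spindle checkpoint protein, at 2.87 ± 0.25, Mki67, a marker of proliferation, at 2.63 ± 0.33, Cdk1 at 2.26 ± 0.25 and Top2a at 1.93 ± 0.22. Without mouse 3 of 9 weeks Tyrp1 was higher by 5.01 and Mki67 by 3.24, and without mouse 1 Tyrp1 by 3.28. The cell division list had adjusted p = 2.87e-13 in camera, and adjusted p = 0.0413 with an estimated correlation. Cholesterol synthesis genes were higher in 11 of 16 cases and lower in 1, the same numbers adjusted over the list alone, with Sqle at 1.51 ± 0.16. Camera gave the cholesterol synthesis list adjusted p = 0.0039, and adjusted p = 0.284 with an estimated correlation.

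Skeletal muscle genes were lower in growth in 23 of 27 cases and higher in 2, or 24 and 2 adjusted over the list alone, with Myh4 at -4.81 ± 0.2 and Pygm at -4.57 ± 0.12. For the skeletal muscle list camera gave adjusted p = 9.70e-19, and adjusted p = 0.0413 with an estimated correlation. Adipocyte genes were lower in 15 of 20 cases and higher in 2, the same numbers adjusted over the list alone, with Thrsp, a regulator of lipid synthesis, at -4.94 ± 0.27 and Slc2a4 at -4.25 ± 0.14. The adipocyte list had adjusted p = 6.83e-07 in camera, and adjusted p = 0.0913 with an estimated correlation. Macrophage and dendritic cell genes were lower in 12 of 14 cases, also 12 adjusted over the list alone, with Lyz2 at -3.53 ± 0.16 and C1qb at -3.21 ± 0.25. Camera gave the macrophage list adjusted p = 6.83e-07, and adjusted p = 0.138 with an estimated correlation. Interferon response genes were lower in 12 of 15 cases, also 12 adjusted over the list alone, with Psmb9 at -3.73 ± 0.42. For the interferon list camera gave adjusted p = 1.84e-06, and adjusted p = 0.101 with an estimated correlation. Genes of class II antigen presentation were lower in 6 of 11 cases, or 7 adjusted over the list alone, with Cd74 at -3.18 ± 0.15. The class II list had adjusted p = 2.89e-04 in camera, and adjusted p = 0.0801 with an estimated correlation. Its mean score rose from -1.69 on day 1 to -0.29 on day 14, 0.58 on day 23 and 0.85 at 9 weeks. That of the hair shaft list instead fell from 2.53 on day 17 to -3.19 on day 23. Endothelial genes were lower in 6 of 12 cases, or 8 adjusted over the list alone, with Vwf, the von Willebrand factor, at -1.5 ± 0.15. Camera gave the endothelial list adjusted p = 0.0035, and adjusted p = 0.0801 with an estimated correlation. Oxidative phosphorylation genes were lower in 46 of 69 cases and higher in 5, or 49 and 5 adjusted over the list alone, with Cox7a1, a subunit of heart and muscle, at -3.56 ± 0.3. For the oxidative phosphorylation list camera gave adjusted p = 3.78e-08, and adjusted p = 0.0913 with an estimated correlation. The 3' over 5' ratio of Gapdh was 1.03 ± 0.12 on day 6, 0.93 ± 0.01 on day 14 and 1.02 ± 0.07 at 9 weeks (SD, n = 3). That of Actb was 1.21 ± 0.12, 1.24 ± 0.06 and 1.05 ± 0.1.

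Of 13 circadian clock genes 6 were lower in growth, also 6 adjusted over the list alone, with Dbp at -3 ± 0.23, Per2 at -2.38 ± 0.28, Per1 at -1.78 ± 0.15 and Nr1d2 at -1.65 ± 0.11. Dbp had at most 42.1 units on days 6 and 14, and Per2 at most 30.1 on day 6. With the floor at 32.7 units, the changes of these 2 genes may be understated. The time of day at which skin was taken is not given in the sources used here. The clock list had adjusted p = 0.0028 in camera, and adjusted p = 0.0413 with an estimated correlation. Genes of stress and immediate early response were lower in 11 of 20 cases and higher in 3, the same numbers adjusted over the list alone, with the phosphatase Dusp1 at -2.08 ± 0.15. Camera gave the stress response list adjusted p = 0.0496, and adjusted p = 0.0913 with an estimated correlation. That call was lost after quantile normalisation (adjusted p = 0.0508), with a higher floor (adjusted p = 0.0539), with a covariate for both sex markers (adjusted p = 0.0504), and without mouse 2 or 3 of day 6, mouse 1 or 3 of day 14, mouse 1 of day 17, mouse 3 of day 23 or mouse 1 or 3 of 9 weeks (adjusted p between 0.05 and 0.0718). The largest decreases were those of Zbtb16 at -5.52 ± 0.29, Inmt at -5.24 ± 0.42, Aldh1a1, a retinaldehyde dehydrogenase, at -5.15 ± 0.14 and Gpx3, a secreted glutathione peroxidase, at -4.96 ± 0.18. In limma, 2385 probe sets were higher in growth and 1941 lower.

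**Figure D3:**
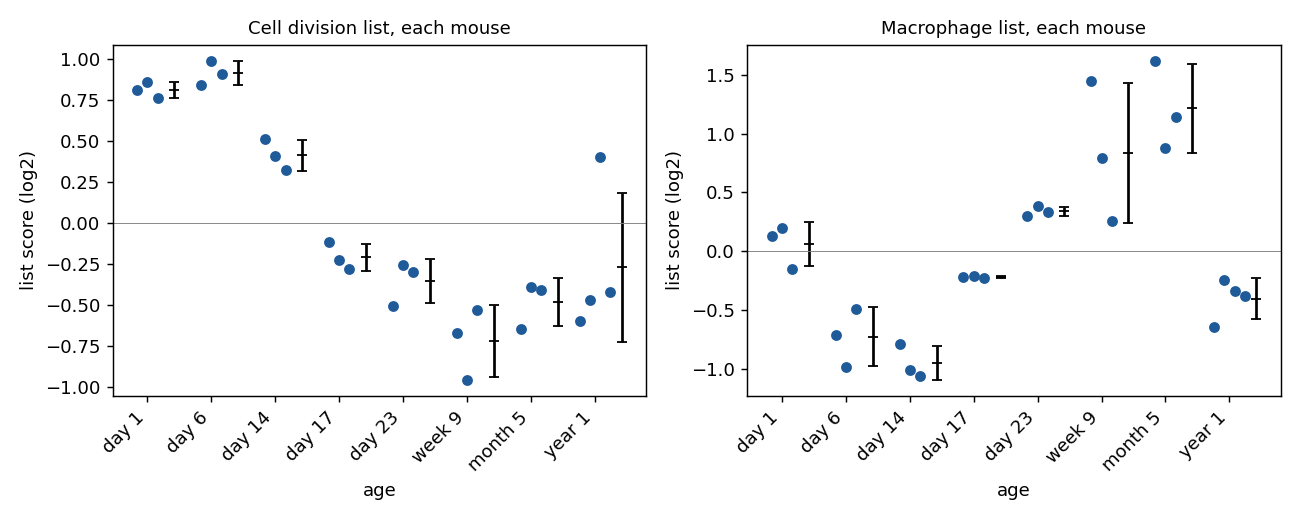
Points are the scores of single mice at each age for the cell division and the macrophage list, on the log2 scale relative to the mean of 25 arrays; black marks give the mean and SD. At 1 year the macrophage scores lay between -0.65 and -0.25, below the 0.88 to 1.62 at 5 months.

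In limma, 209 probe sets were higher and 171 lower at 5 months than at 9 weeks, among them Thbs2, a matrix protein, with a log2 change of 2.16 ± 0.33 (SE, 3 mice per age), Dnajb9 with 2.39 ± 0.28, Thrsp with -3 ± 0.59 and Nos3, the endothelial nitric oxide synthase, with -2.84 ± 0.53. Genes of oxidative phosphorylation were lower in 7 of 69 cases, or 11 adjusted over the list alone, with Cyc1 at -1.09 ± 0.16. For the oxidative phosphorylation list camera gave adjusted p = 2.36e-06, and adjusted p = 0.996 with an estimated correlation. No gene of the 27 of skeletal muscle passed, nor did any adjusted over the list alone, and the list had a median of -0.77. The skeletal muscle list had adjusted p = 3.38e-05 in camera, and adjusted p = 0.996 with an estimated correlation. Ribosomal protein genes were lower in 7 of 26 cases, or 10 adjusted over the list alone, with Rps24 at -0.92 ± 0.15. Camera gave the ribosomal protein list adjusted p = 1.29e-05, and adjusted p = 0.996 with an estimated correlation. After quantile normalisation the ribosomal median turned from -0.33 to 0.03 (adjusted p = 0.933), and the call of Rps24 was lost. The 3' over 5' ratio was 1.02 ± 0.07 at 9 weeks and 0.9 ± 0.03 at 5 months for Gapdh, and 1.05 ± 0.1 and 1.24 ± 0.06 for Actb (SD, n = 3). Adipocyte genes were lower in 3 of 20 cases, or 4 adjusted over the list alone, with Cidec, a lipid droplet protein, at -1.45 ± 0.31 (camera, adjusted p = 0.0124, and adjusted p = 0.996 with an estimated correlation), a call lost after quantile normalisation (adjusted p = 0.117) and without mouse 2 of 9 weeks (adjusted p = 0.291).

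The count of 380 at 5 months against 9 weeks rested on single mice, and each gene named for it lost its call without at least 1 of them. The count was 2 without mouse 1 of 5 months, 3 without mouse 2, 11 without mouse 3, 11, 3 and 194 without mice 1, 2 and 3 of 9 weeks, and 170, 669 and 85 without mice 2, 3 and 4 of 1 year, whose spread enters the fit. It was 1517 when the 25 arrays shared 1 fit, 1339 with array weights, 213 without an intensity trend and 242 with the sex marker covariate. Of the calls 55% were higher, and 36.9% were with arrays centred on their medians.

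At 1 year, against 5 months, macrophage and dendritic cell genes fell in 12 of 14 cases, also 12 adjusted over the list alone. Lyz2 had a mean of 5130 ± 1598 units at 5 months (SD, n = 3) and 982.3 ± 125.1 at 1 year (SD, n = 4), and Mrc1 changed by -2.41 ± 0.32 (log2 change and SE). The list had a median change of -1.97 (camera, adjusted p = 3.96e-08, and adjusted p = 0.458 with an estimated correlation). Ms4a6c, of a family of leukocyte membrane proteins, and Mmp12, the macrophage elastase, fell by 3.01 ± 0.4 and 3.64 ± 0.66, the latter not past the test with a higher floor, at -4.35 without mouse 1 of 5 months and -2.77 without mouse 2. Interferon response genes fell in 6 of 15 cases, or 8 adjusted over the list alone, with Ifi204 at -2.13 ± 0.38. For the interferon list camera gave adjusted p = 4.69e-05, and adjusted p = 0.559 with an estimated correlation. Genes of neutrophils and acute inflammation fell in 2 of 9 cases, or 3 adjusted over the list alone (camera, adjusted p = 0.0288, and adjusted p = 0.458 with an estimated correlation), a call lost without mouse 2 of 5 months (adjusted p = 0.087) or mouse 1 of 1 year (adjusted p = 0.0514) and with the probe sets of a gene averaged (adjusted p = 0.0598). The male marker Eif2s3y was alone above the floor in all 4 mice of 1 year and in mouse 2 of 5 months, and mice 1 and 3 of 5 months had Xist alone. With the difference of both markers as a covariate, an alternative chosen after the data were seen, the macrophage median was -1.34 (camera, adjusted p = 5.49e-08, and adjusted p = 0.545 with an estimated correlation), 3 members passed instead of 12, and Ifi204 did not pass.

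Cholesterol synthesis genes rose in 7 of 16 cases, with 10 higher and 1 lower adjusted over the list alone, among them Fdps at 1.1 ± 0.2, which did not pass with the sex marker covariate. The cholesterol synthesis list had adjusted p = 1.37e-04 in camera, and adjusted p = 0.458 with an estimated correlation. Genes of oxidative phosphorylation rose in 18 of 69 cases and fell in 1, or 25 and 1 adjusted over the list alone, with Cyc1 at 1.28 ± 0.15. Camera gave the oxidative phosphorylation list adjusted p = 4.90e-08, and adjusted p = 0.678 with an estimated correlation. Ribosomal protein genes rose in 14 of 26 cases, with 17 higher and 1 lower adjusted over the list alone, among them Rps24 at 1.09 ± 0.14. For the ribosomal protein list camera gave adjusted p = 3.07e-07, and adjusted p = 0.458 with an estimated correlation. Quantile normalisation turned the ribosomal median from 0.52 to -0.02 (adjusted p = 0.984) and ended the call of Rps24. The 3' over 5' ratio of Gapdh was 0.9 ± 0.03 at 5 months (SD, n = 3) and 1.16 ± 0.08 at 1 year (SD, n = 4), and that of Actb 1.24 ± 0.06 and 1.09 ± 0.15. The largest increases were those of Smyd2, a lysine methyltransferase, at 3.23 ± 0.37 and Abhd8 at 2.27 ± 0.27.

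No hair shaft gene passed at 1 year against 5 months, nor did any adjusted over the list alone, and the list had a median of 2.53. The hair shaft list had adjusted p = 0.0033 in camera, and adjusted p = 0.678 with an estimated correlation. The median was 3.83 without mouse 2 of 5 months and 3.98 without mouse 1 of 1 year, and 1.87, 1.86 and 1.67 without mouse 1 or 3 of 5 months and mouse 3 of 1 year. The hair shaft call was lost without mouse 3 of 5 months (adjusted p = 0.0518) or mouse 3 of 1 year (adjusted p = 0.0658), and the median turned to -0.8 with the sex marker covariate (adjusted p = 0.641). Skeletal muscle genes rose in 2 of 27 cases, and in none adjusted over the list alone (camera, adjusted p = 0.0033, and adjusted p = 0.678 with an estimated correlation), a call lost after quantile normalisation (adjusted p = 0.475) and without mouse 1 of 1 year (adjusted p = 0.0852). Genes of the hair follicle bulge fell in 4 of 15 cases, or 6 adjusted over the list alone. Camera gave the bulge list adjusted p = 0.0466, and adjusted p = 0.559 with an estimated correlation. The bulge call was lost with a higher floor, with the probe sets of a gene averaged, with the sex marker covariate (adjusted p = 0.163), and without mouse 3 of 9 weeks, mouse 1 or 3 of 5 months or mouse 1 of 1 year (adjusted p between 0.051 and 0.121).

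In limma, 508 probe sets were higher and 773 lower at 1 year. The share of higher calls was 39.7%, and it was 57.6% with arrays centred on their medians, which moved the median change of all probe sets from -0.074 to 0.044, and the median change of ribosomal proteins to 0.63 and of the bulge to -0.29. The count of 1281 was 89 with the sex marker covariate, 2596 when the 25 arrays shared 1 fit and 2315 with array weights. Without mice 1, 2 and 3 of 5 months it was 268, 822 and 537, and without mice 2 and 4 of 1 year 759 and 786.

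The labels name a study that used the variance between replicates, so the spread between mice at 5 months and 1 year (5 degrees of freedom) was set against that at the 6 earlier ages (12 degrees of freedom). The spread was larger for 754 probe sets (1-sided F test, adjusted p under 0.05) and smaller for 14, with a median variance ratio of 1.57 over all probe sets. Skeletal muscle genes had a median ratio of 8.21 and 16 of 27 were called, genes of oxidative phosphorylation had 4.3 with 21 of 69, hair shaft genes 5.43 with 7 of 21, inner root sheath genes 5.81 with 3 of 9, bulge genes 4.68 with 5 of 15 and circadian clock genes 4.23 with 5 of 13. Each of these medians lay above 99% of those of random lists of like expression. Random lists hold unrelated genes, while 1 mouse can move a whole list of related ones, so this rank is a description only. Macrophage and dendritic cell genes had a median ratio of 1.08 and B cell genes 0.91, with none called. Krt6a, a keratin of the follicle's companion layer, had the highest ratio, with 1140.3 units in mouse 1 of 1 year and 6491 to 10592 in the others of that age. Fhl1, a muscle LIM protein, Col4a1, Gbe1, Vtn, Ldha, Ctsb, Amot, Bin1 and Tnnt3 followed, with ratios between 71.95 and 41.69. Of these, Col4a1 did not pass without mouse 1 of 1 year (ratio 6.41) nor Tnnt3 without mouse 3 (ratio 8.97), and with a higher floor the ratio was 0.616 for Vtn and 5.96 for Gbe1, which did not pass. With 5 months alone 9 of the 10, all but Vtn, did not pass, with a ratio of 0.259 for Fhl1. With days 14 and 23 as the only young ages Col4a1, Ldha, Ctsb, Amot, Bin1 and Tnnt3 did not pass.

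Of probe sets over 4-fold higher in growth than at 9 weeks 34.4% were more variable at the older ages, of those over 4-fold lower 30.8%, and of those that differed by less than 2-fold 6.1%. Of the 754 probe sets, 720 were among those that differed between the 6 earlier ages (Fisher's exact test, 2-sided, p = 5.25e-40, odds ratio 6.09), but both calls use the spread of the young ages and are not independent. The count was 3 with 5 months alone and 1034 with 1 year alone, and 265 and 137 without mice 1 and 3 of 1 year. With 9 weeks left out of the young ages it was 1362, and with days 14 and 23 as the only young ages 171, both chosen after the data were seen.

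**Figure D4:**
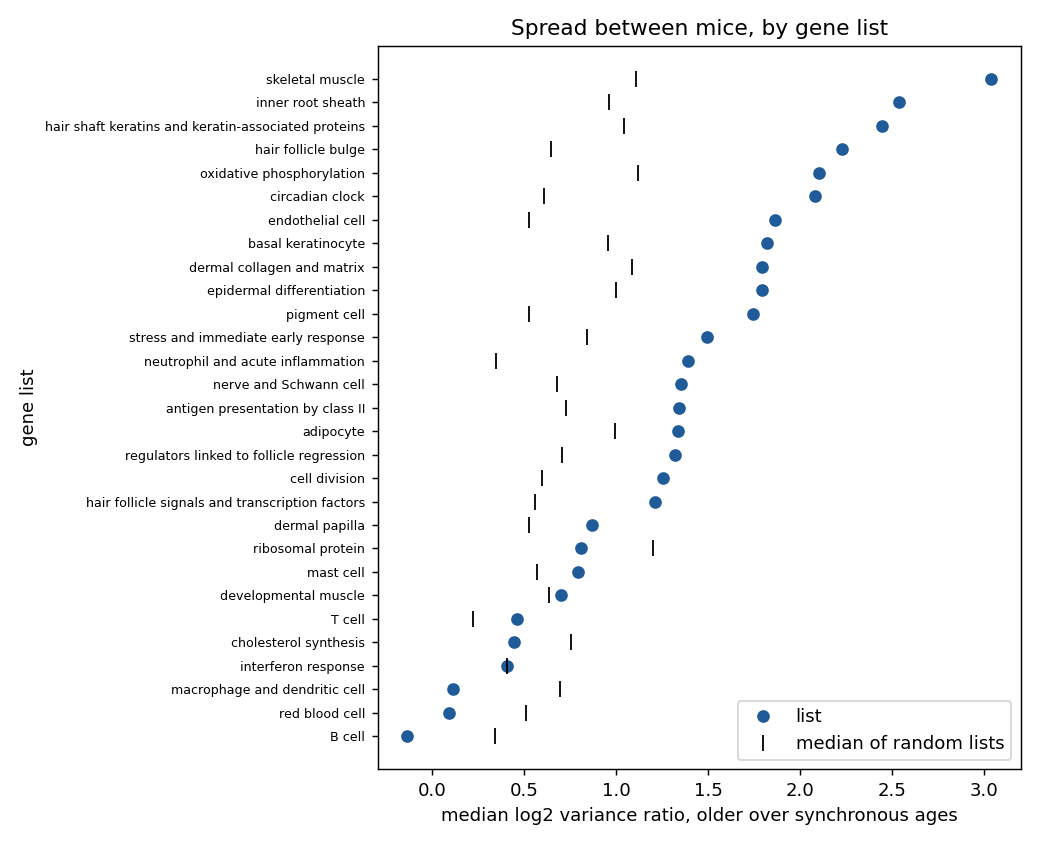
Points give the median log2 variance ratio of older over earlier ages for each of 29 gene lists, and vertical ticks the median of 10000 random lists of like expression. Skeletal muscle lies highest at 3.04.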

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

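No test in this part was chosen after the result was seen. At 1 year, the only age with 4 mice, the gap between 1 mouse and the nearest other was divided by the range of all 4. Of 29 list scores 2 and of 48 genes 5 exceeded the critical value for 4 samples, and chance alone does so in about 1 of 20 groups. The epidermal differentiation score was -0.56 in mouse 1 and 0.01 to 0.08 in the others, a ratio of 0.891. The basal keratinocyte score was -0.09 in mouse 3 and 0.18 to 0.21 in the others, a ratio of 0.893. Rpl38, a ribosomal protein gene, had a log2 value of 8.04 in mouse 3 and 6.77 to 6.79 in the others, a ratio of 0.983. Nfatc1, a transcription factor of bulge cells, had 6.8 in mouse 3 and 8.19 to 8.4 in the others, a ratio of 0.866. Ifit1, induced by interferon, had 6.04 in mouse 1 and at most 5.12 in the others, a ratio of 0.911. Fgf18 in mouse 2 (6.74) and Itgam, an integrin of myeloid cells, in mouse 4 (5.83) were each the only value above the floor of 5.03, which gives a ratio of 1. No explanation was tested for these values.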

How the results depend on the processing

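The covariate for both sex markers, the fit without 9 weeks and the fit with days 14 and 23 as the only young ages were chosen after the data were seen. Of 392 gene results 278 kept their direction and their side of the threshold under every alternative that tested them. A call was lost under at least 1 alternative for 113, and 2 turned. The stricter filter left 347 of the 392 to test. Of 79 list calls 5 held with an estimated correlation (developing muscle on day 6 against day 1, and pigment cell, cell division, skeletal muscle and circadian clock in growth against 9 weeks) and kept their call under every other alternative run, and 74 were lost under at least 1. Fitting all 25 arrays together gave 951 probe sets for day 14 against day 6, 1517 for 5 months against 9 weeks and 2596 for 1 year against 5 months, and fitting only the groups compared gave 1585 for 9 weeks against day 23. Array weights gave 1339 for 5 months against 9 weeks and 2315 for 1 year against 5 months, and the fit without an intensity trend gave 213 for the former. With the sex marker covariate the counts were 242 and 89, and the hair shaft list at 1 year against 5 months turned to -0.803. The cause was not tested for any of these. The count of probe sets more variable at the older ages was 3 with 5 months alone, where Fhl1 had a ratio of 0.259, 1362 without 9 weeks among the young ages and 171 with days 14 and 23 alone, fits with fewer arrays. A floor at the 40th percentile, which raises low values, turned the ratio of Vtn to 0.616. The number of probe sets highest on day 1 was 970 with arrays centred on their medians.

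Same-numbered mice of different ages did not deviate together, so the numbers were not taken to pair samples: over 84 pairs of arrays the mean correlation of deviations was 0.004, from -0.352 to 0.388, and 8 exceeded 0.1, against a mean of -0.002 over 189 other pairs. With the replicate number as a block limma called 0 probe sets for 5 months against 9 weeks (1671 at an unadjusted p under 0.05), 388 for 1 year against 5 months and 237 for the variance test. The block also ended the bulge call at 9 weeks against day 23 and 36 gene calls, 20 at 5 months against 9 weeks, 15 at 1 year against 5 months and the variance ratio of Vtn, and other counts stayed within 1.5 times.

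Leaving out 1 mouse at a time gave 2 to 669 probe sets for 5 months against 9 weeks, 268 to 1373 for 1 year against 5 months and 137 to 1096 for the variance test. The lowest came without mouse 1 of 5 months, mouse 1 of 5 months and mouse 3 of 1 year. All other counts stayed within 1.5 times, from 1009 to 1791 for day 14 against day 6 and from 6691 to 7086 among the 6 young ages. Signal over background limits genes near the floor: 1.01% to 3.7% of values on an array lay at it, and a change against a group at the floor is a lower bound.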

Other observations

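Tests chosen only after the result was seen were those of RNA of day 6 skin alone, of dilution, of the sex of the mouse and of a mouse ahead in growth at 9 weeks, of the spread between mice, the share of macrophages and the covariates for the macrophage score, and the choices of other ages for the variance test. The genes described per mouse here were also chosen after their values were seen. Ucp1, the uncoupling protein of brown fat, had 170.5 to 1077.3 intensity units on day 1, 76.3 to 422.9 on day 6, 5.9 to 14.4 on day 14, 263 to 715.8 on day 17 and 54.2 to 436.6 on day 23, and at most 18.3 in every mouse of 9 weeks or older. Glycam1, a mucin-like protein of lymph node vessels, had 154.2 to 449.6 units on day 17, 584.8, 1346.1 and 14.5 in mice 1, 2 and 3 of day 23, and at most 28.4 in every mouse of the other ages. Mup3, of the family of major urinary proteins, had 533.1 to 796 units on day 23 and 1659.4 to 5316 at 9 weeks, and at most 276.9 in every mouse of earlier ages.

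Dbp, a target of the circadian clock, had at most 42.1 units in each of the 12 mice up to day 17. It had 443.8 to 572.8 on day 23, 205 to 331.3 at 9 weeks, 340.3 to 1022.8 at 5 months and 120.3 to 271.2 at 1 year. The time of day at which skin was taken is not given in the sources used here, and no explanation was tested.

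At 9 weeks mouse 3 had a hair shaft score of 1.67, against -3.16 and -3.25 in mice 1 and 2. RNA of day 6 skin mixed into the sample was argued against by 4 matrix genes alone, 3 of them clear of the floor. They stood at a median of -6.7% of their day 6 level (upper quartile 0.4%), and hair genes at 57.9% (lower quartile 45.8%). Dilution could not decide for day 6: the fall of probe sets high at rest had an upper quartile of 49.7%, above the lower quartile of hair genes. RNA of day 14 or day 17 skin stays open, as only 1 and 2 matrix genes could be tested (-12.7% and -6%, against 34.3% and 45.2% for hair genes), and probe sets high at rest fell in mouse 3 by medians of 25.1%, 27.2% and 20.8% towards days 6, 14 and 17, against 4.7%, 9.7% and 17.5% in mouse 1 and 1.4%, 1.1% and -0.9% in mouse 2. Of the mice of 9 weeks or older, 5 of 6 with the male marker alone scored above all 4 with the female marker alone, but mouse 1 of 1 year had the male marker and -3.52, and as 1 mouse excludes nothing, sex stays open. The pigment cell, follicle signal and cell division scores were all 3 higher in mouse 3 than in the others, which is consistent with a mouse that had entered growth ahead of them, but mixed RNA could give the same and this remains a hypothesis.

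Pooled over 5 months and 1 year the spread between mice was larger than before, with 3 probe sets called for 5 months alone (median ratio 0.854) and 1034 for 1 year alone (1.72). RNA of more than 1 mouse on the young arrays with both sex markers could have narrowed the young spread. The median variance ratio of days 14 and 23, without such arrays, over days 6 and 17, where every array was such, was 0.955. But the median SD was 0.206 on day 6 and 0.156 on day 17, against 0.173 on day 14 and 0.176 on day 23. As the 2 ages with such arrays lay on either side, the ratio cannot decide, and this stays open. Of 29 lists 14 lay above 95% of random lists of like expression, which noise of equal size and independent between genes would not give. Members of a list can move together while those of a random list are unrelated, so noise shared by genes stays open. Noisier arrays with unequal effects stay open too, with a lowest median of 0.113 on the log2 scale among lists of 10 or more genes. Of the 28 choices of 2 of the 8 ages, 2 gave as many probe sets, the real one with 754 and 9 weeks with 1 year at 1665. Chance in the choice of ages could thus not be excluded, and pairs with 1 year gave at least 386 against at most 82 without it. The median SD between mice was 0.279 at 9 weeks, 0.224 at 5 months and 0.327 at 1 year, so the spread did not grow in order of age. A loss of synchrony between mice with age is a candidate explanation, and as few mice and 1 age carry the result it stays a hypothesis. The skeletal muscle list had the highest median ratio, 8.21 against 5.43 for hair shaft genes, so the larger spread was not limited to follicle genes. Neither the muscle content of the samples nor RNA quality was tested.

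Macrophage genes were lower at 1 year than at 5 months, with a median log2 change of -1.968 over 14 members and scores of -0.65 to -0.25 against 0.88 to 1.62. Sex acting alike at every age did not account for the whole change in a fit with the sex marker covariate. The score changed by -1.17 ± 0.31 (SE; -1.62 ± 0.3 without it) and the list median was -1.34 (camera, adjusted p = 5.49e-08, and adjusted p = 0.545 with an estimated correlation). Of the members 3 passed instead of 12, at a median SE of 0.32 instead of 0.33, and 89 probe sets passed in all instead of 1281. The hair shaft median turned from 2.53 to -0.8. The slope for sex rests largely on mouse 3 of 9 weeks and mouse 2 of 5 months, the only ones there with the male marker alone. They also had the highest hair shaft scores of their ages, so this fit cannot tell sex from hair phase. Hair growth phase likewise did not account for the whole change in its fit, with a change of -1.49 ± 0.33 with the hair shaft score as the covariate and -1.15 ± 0.33 with both. Either stays open as a part, or where its effect differs with age, since 1 mouse bears on each bound of 0.5 set beforehand. Mouse 2 of 5 months was the only one there with the male marker alone. It lay at 0.72 between 1 year at 0 and its age mates at 1. Mouse 1 of 1 year, with the lowest hair shaft score, lay at -0.21 between its age mates at 0 and 5 months at 1. Macrophage genes were also lower in growth than at 9 weeks (median -1.74), but there age differed as well as hair phase. A lower share of macrophages may be part of it, but members changed by -2.92 to 0.25 and a share alone would move them alike, so that share and level per cell cannot be told apart, and an effect of age stays a hypothesis.

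Other splits of the same arrays were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05, with the real split the only 1 to reach its value: 3235 probe sets for day 6 against day 1 (highest other 1), 1464 for day 14 against day 6 (2), 2671 for day 17 against day 14 (2), 3382 for day 23 against day 17 (0), 2743 for 9 weeks against day 23 (3) and 380 for 5 months against 9 weeks (1). Chance was excluded for the 6 young ages (1 of 100, 6996 against at most 194). For 1 year against 5 months the real split alone, 1 of 35 or a share of 0.029, reached 1281, and the others gave at most 9. That share is the smallest that 35 splits can give and was not adjusted over the comparisons. It cannot tell age from the sex markers, which differed with age there. For growth against 9 weeks 1 of 100 splits, the real one, reached 4326, and the others gave at most 3950. Those splits could exchange arrays of days 6 and 14 and leave 9 weeks whole, which hardly changes the comparison. So 3950 is not a level that chance alone gives, and chance is not called excluded there.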
